A study of Arabidopsis thaliana with 6 samples.

How the data were processed

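RNA was measured in 6 libraries of Arabidopsis thaliana seedlings, 2 for each of 3 genotypes: Col-0 (wild type), apc8-1 and nrpe1-12. Ribosomal RNA had been depleted from total RNA before the libraries were made. Per the submitters' processing notes, the TAIR10 genome, TopHat2 2.0.13, Cufflinks 2.2.1 and Cuffnorm 2.2.1 were used. The deposited table holds the authors' FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of a library) for each library and locus. It has 32594 loci, of which 403 merge several genes, 122 are unannotated intergenic loci and 66 are unannotated loci antisense to a gene. The strand on which fragments were counted is not stated, so levels of antisense loci are uncertain. Fragments of near-identical paralogs cannot be separated in this table, so the split of values between the RBCS genes, the LHCB1 genes, the H3.1 genes, or CDC20.1 and CDC20.2, is uncertain. The gene names came from the RefSeq annotation, which matched 31393 of the 32069 loci with 1 gene name (97.9%). Coordinates are those of the deposited table.

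No fragment totals come with the table. The size of 1 fragment in each library was estimated from the steps between low values of loci longer than 1500 bases with a single exon, of which 91.7 to 95.0% lay within 0.15 of a whole number of fragments. Columns of Col-0 and apc8-1 carry replicate numbers. Both nrpe1-12 columns carry the same name, so they are called library a and library b in the order of the table.

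The values were transformed to log2(FPKM + 1). The 17802 loci with at least 1 FPKM in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) in 1 fit of all 6 libraries, with 3 residual and 4.93 prior degrees of freedom. A locus was called changed at a Benjamini-Hochberg adjusted p below 0.05. The comparisons were apc8-1 against Col-0, nrpe1-12 against Col-0, and apc8-1 against nrpe1-12. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333, so p-values rest on the spread pooled across loci and libraries. Tested on simulated data with 17456 genes, this procedure recovered 29 of 67 changes of 0.5 on the log2 scale in apc8-1 against Col-0, 62 of 67 changes of 1 and 65 of 66 changes of 2, with 8 false calls among 164. In nrpe1-12 against Col-0 it recovered 34 of 67, 63 of 67 and 63 of 66, with 15 false calls among 175. The simulation changed far fewer genes than were called in the data and drew normal noise with the fitted spread. These rates therefore need not hold for the data.

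The gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. There were 17 lists with 262 genes, of which 256 are in the table and 219 were tested. They cover APC/C subunits and activators, RdDM machinery, DNA methylation maintenance and demethylation, genes known to be silenced by DNA methylation, G2/M phase, S phase and DNA replication, DNA damage response, auxin response, salicylic acid defence, jasmonate response, heat shock, cold and abscisic acid, the circadian clock, photosynthesis, root markers, flowering and anthocyanin. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The p-values were adjusted over the fixed lists of each comparison. Shares of called loci among transposable element genes, pseudogenes, annotated long noncoding RNA genes, unannotated antisense loci and unannotated intergenic loci were compared with those of all other tested loci by two-sided Fisher's exact tests, adjusted over the 5 classes and both directions. These tests treat loci as independent, although some intergenic loci are close neighbours. The correlation and covariance of the changes in both mutants were set against 20 simulations in which groups without an effect shared the Col-0 libraries. Overlap was also computed with a different single Col-0 library for each mutant, in both assignments, which was added after the results had been seen.

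The rule for named genes took the 10 loci with the largest increase and the 10 with the largest decrease in each mutant against Col-0, and the 5 and 5 in apc8-1 against nrpe1-12, among called loci with a mean of at least 1 FPKM in the higher group and no overlap between libraries. It added up to 4 members per list with the smallest p, APC8, NRPE1, DMS3, ROS1, SDC and FWA in every comparison, and the noncoding and transposable element loci with the largest changes. The rule's result for 1 entry is not reported here. After the results had been seen, 4 further lists were added (phosphate starvation, iron deficiency, nitrate induced and leaf senescence genes), and they were tested without the 9 genes in which the patterns had been noticed. Their p-values were adjusted over these 4 lists alone.

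The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a filter of 5 FPKM in 2 libraries, median-of-ratios scaling, quantile normalization, fits of only the 2 genotypes compared, eBayes without trend, organelle and ribosomal RNA genes left out, a minimum change of 2-fold, a replicate block, and each library left out in turn. Where organelle and ribosomal RNA genes were left out, each library was also rescaled to the same summed FPKM of the remaining loci. The effects of these steps cannot be told apart. Leaving out loci listed at 0 in any library was added after the results had been seen. No paired analysis was possible for nrpe1-12 because its columns carry no replicate number. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.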

Results

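Total RNA of Arabidopsis thaliana seedlings collected at 14 days was sequenced for 3 genotypes, with 2 libraries each. Col-0 is the wild type. The apc8-1 line carries a mutant allele of APC8, a subunit of the anaphase promoting complex/cyclosome (APC/C), the ubiquitin ligase that marks mitotic cyclins for degradation. The nrpe1-12 line carries a mutant allele of NRPE1, the largest subunit of RNA polymerase V, which makes the scaffold transcripts of RNA-directed DNA methylation (RdDM). The study connects the APC/C with DMS3, an RdDM protein, so the comparisons asked which transcripts each allele alters and how far the altered sets overlap. Between 16828 and 17301 loci reached 1 FPKM in a library. A level of 1 FPKM corresponded to an estimated 17.9 and 13.5 fragments per kilobase in the Col-0 libraries, 14.9 and 15.2 in apc8-1 and 15.6 and 13.1 in nrpe1-12. With the gene rbcL (ATCG00490) left out, chloroplast transcripts made up 24.1 and 24.4% of the FPKM in the Col-0 libraries, 28.4 and 30.2% in apc8-1 and 28.6 and 29.0% in nrpe1-12, so both mutants stood above Col-0. The gene rbcL was given 45404.5 FPKM in Col-0 replicate 2, which had a share of 29.3% with it, and is listed at 0 in the other 5 libraries. The 2 Col-0 libraries disagree on rbcL, so its values of 0 cannot be read as absence of transcript. Across tested loci, which are not independent replicates, log2(FPKM + 1) correlated at r = 0.989 to 0.991 within a genotype and at 0.954 to 0.969 between genotypes. No source used here states that the duplicates are separate cultures, so p-values measure only the spread between these samples. Fold changes are differences of log2(FPKM + 1) and understate the changes of loci with low levels. Means are given with the SD of n = 2 libraries, and coordinates are TAIR10.

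APC8 (AT3G48150, chromosome 3, 17779653 to 17782645) had 1.29 and 1.64 FPKM in the Col-0 libraries, 1.80 and 1.93 in apc8-1, and 1.51 and 1.48 in nrpe1-12. Its log2 fold change was 0.22 in apc8-1 (SE 0.15, adjusted p = 0.306) and 0.02 in nrpe1-12 (adjusted p = 0.937), and neither passed the test. NRPE1 (AT2G40030, chromosome 2, 16714494 to 16723631) had 2.71 and 2.91 FPKM in Col-0, 3.04 and 3.29 in apc8-1, and 6.46 and 5.94 in the libraries labelled nrpe1-12, where it rose by 0.92 on the log2 scale (SE 0.12, adjusted p = 9.77e-04). The kind of lesion in either allele is not given in the sources used here, so the transcript levels of APC8 and NRPE1 cannot check the genotype labels. DMS3 (AT3G49250), which acts with RNA polymerase V in RdDM, had 2.79 ± 0.158 FPKM in Col-0, 3.42 ± 0.139 in apc8-1 and 2.84 ± 0.184 in nrpe1-12. Its transcript passed the test in neither mutant (adjusted p = 0.222 and 0.929).

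Seedlings of apc8-1 had more transcript of 11 of 23 G2/M phase genes and of nuclear photosynthesis genes than Col-0, and less of anthocyanin genes. None of these 3 lists passed camera with an estimated correlation (adjusted p = 0.122, 0.274 and 0.122). CDC20.1 (AT4G33270), an activator that brings substrates to the APC/C, rose from 5.64 ± 0.0138 to 12.98 ± 0.694 FPKM (log2 fold change 1.07, SE 0.10, adjusted p = 1.42e-04). PAP1 (AT1G56650), a MYB regulator of anthocyanin synthesis, fell from 16.1 ± 1.64 to 2.02 ± 0.429 FPKM (log2 fold change -2.51, SE 0.13, adjusted p = 8.70e-06). In total 2511 loci were called higher and 2873 lower, 30.2% of those tested, and 158 and 733 of these changed at least 2-fold. Without Col-0 replicate 1 the number of calls was 3252 in place of 5384, and without Col-0 replicate 2 it was 3348. With organelle and ribosomal RNA genes left out and libraries rescaled to equal summed FPKM of the remaining loci, the median over all loci moved to -0.07. Then 1736 loci were called higher and 3693 lower, so 32.0% of the calls were increases in place of 46.6%.

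The largest increases in apc8-1 included BT2 (AT3G48360), a BTB and TAZ domain protein gene, which rose from 4.60 ± 0.555 to 87.3 ± 2.22 FPKM (log2 fold change 3.98, adjusted p = 2.24e-07), and its relative BT1 (log2 fold change 2.95). TCH4 (AT5G57560), a touch-induced xyloglucan endotransglucosylase gene, rose from 25.0 ± 1.00 to 192 ± 8.57 FPKM (log2 fold change 2.89). IMA2 (AT1G47395), which encodes a peptide of iron uptake signalling, was listed at 0.349 and 0 FPKM in Col-0 and at 11.4 and 9.21 in apc8-1. An unannotated locus antisense to AT1G13609 was listed at 0 in both Col-0 libraries and at 26.5 and 29.0 FPKM in apc8-1. Among the largest decreases, SAG12 (AT5G45890), a senescence-associated cysteine protease gene, was listed at 75.3 and 75.6 FPKM in Col-0 and at 0.0609 and 0 in apc8-1. PS2 (AT1G73010), a phosphatase gene induced by phosphate starvation, fell from 82.0 ± 1.07 to 4.42 ± 0.0794 FPKM (log2 fold change -3.94). MYB90, a relative of PAP1, fell from 33.1 ± 1.88 to 1.17 ± 0.179 FPKM (log2 fold change -3.98), and BGLU21, a beta-glucosidase gene, from 16.1 ± 0.703 to 0.226 ± 0.0907 FPKM (log2 fold change -3.80).

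Of 23 tested G2/M phase genes 11 rose in apc8-1 and none fell, with 6 to 10 higher when a library was left out and 13 when adjusted over the list alone (median log2 fold change 0.42, adjusted p = 2.00e-05 by camera, adjusted p = 0.122 with an estimated correlation). TPX2, a spindle assembly factor, rose by 0.87, the B-type cyclin CYCB1;2 by 0.81, and KNOLLE, a syntaxin of the cell plate, by 0.72 on the log2 scale. Among 17 APC/C subunits and activators 3 rose, 1 fell and 13 were not called, and the counts were the same when adjusted over the list alone (camera adjusted p = 0.0856). The 3 that rose are activators: CDC20.1, CDC20.2 (log2 fold change 0.80) and CCS52B (log2 fold change 0.92). The subunit APC13 fell (log2 fold change -0.62). The CDC20.2 call was lost without Col-0 replicate 1 (adjusted p = 0.0937), apc8-1 replicate 2 (adjusted p = 0.0820) or the filter on low values (adjusted p = 0.0550), and the APC13 call without any 1 of the Col-0 and apc8-1 libraries (adjusted p = 0.0584 to 0.120) and with quantile normalization (adjusted p = 0.0567). In the DNA damage response list 4 of 8 genes rose and none fell (4 adjusted over the list alone, camera adjusted p = 0.0647). Only 1 of these 8 was called with organelle and ribosomal RNA genes left out. Each of the 4 calls was lost when some single library was left out. Those of BRCA1, GMI1 and PARP1 were also lost in the replicate block (adjusted p = 0.0671, 0.0592 and 0.0586). In the S phase list 1 of 20 genes rose, CDC6 with a log2 fold change of 0.65, and none was called when adjusted over the list alone (camera adjusted p = 0.134). The CDC6 call was lost without either Col-0 replicate 1 (adjusted p = 0.0504), Col-0 replicate 2 (adjusted p = 0.0895) or apc8-1 replicate 2 (adjusted p = 0.0708).

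Of 23 tested RdDM genes 3 rose in apc8-1 and none fell, and none was called when adjusted over the list alone (median 0.15, camera adjusted p = 0.138). The 3 calls, of MORC6, DRM2 and RDM1, were lost without any 1 of the Col-0 and apc8-1 libraries (adjusted p = 0.0614 to 0.151). Those of MORC6 and DRM2 were also lost in the replicate block (adjusted p = 0.0520 and 0.0694), and 1 of 23 was called with organelle and ribosomal RNA genes left out. In the list of DNA methylation maintenance and demethylation 4 of 15 genes rose and none fell, with 5 higher when adjusted over the list alone (camera adjusted p = 0.0599). The calls of SUVH4 and DME were lost in the replicate block (adjusted p = 0.0772 and 0.0745), with median-of-ratios scaling and with organelle and ribosomal RNA genes left out, which each left 2 of 15 higher. That of MET1 was lost without any 1 of the Col-0 and apc8-1 libraries (adjusted p = 0.0544 to 0.116). VIM1, which recruits the maintenance methyltransferase, rose from 7.49 ± 0.0939 to 11.2 ± 0.00728 FPKM (log2 fold change 0.53). ROS1 (AT2G36490), a DNA glycosylase gene of active demethylation, had 14.8 ± 1.12 FPKM in Col-0 and 18.7 ± 0.179 in apc8-1 (log2 fold change 0.32, adjusted p = 0.0534). Only 2 of the 5 genes listed as silenced by DNA methylation were tested (camera adjusted p = 0.695). SDC, an F-box gene of that list, was listed at 1.48 and 0 FPKM in Col-0 and at 0 in both apc8-1 libraries. QQS, also of that list, was listed at 0.582 and 0.588 FPKM in Col-0 and at 4.32 and 1.21 in apc8-1, and was called higher, also when adjusted over the list alone. QQS reached 1 FPKM in 2 libraries only through apc8-1, so it could be called higher but not lower. Without either apc8-1 library it was not tested. The QQS call was lost without either Col-0 library (log2 fold change 1.11 in each case) or either nrpe1-12 library. It was also lost without the filter on low values (adjusted p = 0.120) or the trend (adjusted p = 0.0740). The same held with a pseudocount of 0.1 (adjusted p = 0.0674) and in the fit of 2 genotypes (adjusted p = 0.0651).

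All 14 photosynthesis genes rose in apc8-1, also when adjusted over the list alone (median log2 fold change 0.50, camera adjusted p = 2.06e-08, adjusted p = 0.274 with an estimated correlation). RCA, which encodes Rubisco activase, rose from 1083 ± 73.1 to 1650 ± 85.5 FPKM. With quantile normalization the median was 0.21 (camera adjusted p = 0.0315), and 8 of the 14 were called, all higher. The chloroplast share of the FPKM was higher in apc8-1 too, while the 6 tested root markers had a median of -0.72, with 1 higher and 3 lower. Of 9 anthocyanin genes 7 fell and none rose, with 8 lower when adjusted over the list alone (median log2 fold change -1.46, camera adjusted p = 1.33e-06, adjusted p = 0.122 with an estimated correlation). DFR, which encodes dihydroflavonol reductase, fell from 10.5 ± 0.524 to 1.29 ± 0.0576 FPKM (log2 fold change -2.33), and TT19, a glutathione transferase gene, fell by 2.00 on the log2 scale. The other lists did not pass camera in apc8-1, although the methylation maintenance list passed with quantile normalization (adjusted p = 0.0366). That list and the DNA damage list also passed with organelle and ribosomal RNA genes left out (adjusted p = 0.0492 for each). In the main fit with an estimated correlation camera gave them adjusted p = 0.274 and 0.277. Among 17 jasmonate response genes 2 rose and 7 fell, with the same counts adjusted over the list alone (adjusted p = 0.0599). The repressor genes JAZ7 and JAZ9 rose (log2 fold changes 2.38 and 1.12), while the biosynthesis genes AOC1, LOX2 and AOS fell (log2 fold changes -0.93, -0.86 and -0.79). Among 18 salicylic acid defence genes 4 rose and 8 fell, with 4 and 9 adjusted over the list alone (adjusted p = 0.0647), among them WRKY38 (log2 fold change -2.18) and PBS3 (log2 fold change -1.32) as decreases and PR2 (log2 fold change 0.57) as an increase. Heat shock genes fell in 3 of 7 cases and rose in none, with the same counts adjusted over the list alone (adjusted p = 0.0647), with HSP90.1 at a log2 fold change of -1.30.

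Among 9 cold and abscisic acid genes 2 rose and 5 fell in apc8-1, with the same counts adjusted over the list alone (camera adjusted p = 0.134). KIN1 fell by 1.56 on the log2 scale and RAB18 rose by 0.77. Among 16 auxin response genes 5 rose and 2 fell, with 7 and 2 adjusted over the list alone (adjusted p = 0.152), and IAA29 and IAA14 had log2 fold changes of 0.94 and 0.72. Among 11 circadian clock genes 6 rose and 1 fell, with the same counts adjusted over the list alone and 3 to 6 and 0 to 2 when a library was left out (adjusted p = 0.0640), and PRR7 and CCA1 had log2 fold changes of 0.63 and 0.47. Of 16 root markers in the table only 6 were tested, of which 1 rose and 3 fell, with 1 and 4 adjusted over the list alone and 0 to 1 and 1 to 3 when a library was left out (median -0.72, adjusted p = 0.0647). The nitrate transporter gene NRT2.1 fell from 9.97 ± 0.517 to 0.220 ± 0.153 FPKM. EXPA18, a root hair expansin gene, was listed at 1.68 and 1.53 FPKM in Col-0 and at 0.0805 and 0 in apc8-1. Among 4 flowering genes 1 rose and 1 fell, with the same counts adjusted over the list alone (median 0.03, mean -0.10, adjusted p = 0.924). The increase, of SOC1, was lost without Col-0 replicate 1 (adjusted p = 0.0963) or apc8-1 replicate 1 (adjusted p = 0.0697). The decrease, of FLC, was lost without Col-0 replicate 2 (adjusted p = 0.0589). The median of the flowering list was -0.02 when organelle and ribosomal RNA genes were left out.

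Transposable element genes were called lower in apc8-1 less often than other loci. Only AT2G04460 among 89 tested (1.12%) was lower, against 16.2% of all other tested loci (Fisher's exact test, adjusted p = 4.12e-05). AT2G04460 (chromosome 2, 1547508 to 1549265) fell from 16.3 ± 1.09 to 0.825 ± 0.272 FPKM (log2 fold change -3.25, adjusted p = 2.63e-06). A total of 13 of the 89 (14.6%) were higher, against 14.1% of other loci, among them AT5G35935, which went from 0.281 ± 0.242 to 3.18 ± 0.355 FPKM (log2 fold change 1.72). The tested transposable element genes had a median level of 3.39 FPKM, against 8.42 for loci outside the 5 classes. Some passed the filter only through nrpe1-12, such as AT5G26590 at 0 and AT5G27845 at 0.0151 FPKM in Col-0. Such genes could not be called lower in apc8-1, so the share of decreases depends on the filter. With a filter of 5 FPKM the difference in decreases no longer passed (adjusted p = 0.141). Pseudogenes, long noncoding RNA genes, antisense loci and intergenic loci passed in neither direction (Fisher's exact test, adjusted p = 0.401 to 1). The intergenic locus XLOC_030585 (chromosome 5, 14550485 to 14550826) was listed at 145 and 103 FPKM in Col-0 and at 3.91 and 0 in apc8-1.

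In nrpe1-12 seedlings, loci that were nearly silent in Col-0 had transcripts, and the demethylase gene ROS1 had little. AT5G27845, a transposable element gene (chromosome 5, 9868348 to 9872594), rose from 0.0151 ± 0.00302 to 36.3 ± 0.143 FPKM (log2 fold change 5.20, SE 0.13, adjusted p = 8.93e-07). ROS1 (chromosome 2, 15307950 to 15314807), a gene known to need RdDM for its expression, fell from 14.8 ± 1.12 to 0.990 ± 0.160 FPKM (log2 fold change -2.99, SE 0.11, adjusted p = 3.90e-06). Most tested genes of the jasmonate response (11 of 17), the heat shock response (6 of 7) and photosynthesis (13 of 14) were higher, though none of these lists passed camera with an estimated correlation (adjusted p = 0.213, 0.213 and 0.301). On chromosome 3, AT3G29639 (11471132 to 11481270) rose from 0.156 ± 0.0766 to 33.1 ± 2.40 FPKM (log2 fold change 4.88), and the unannotated locus XLOC_020069 on its left (11470442 to 11470911) from 0.683 ± 0.554 to 43.0 ± 4.97 FPKM (log2 fold change 4.75). The unannotated locus XLOC_020070 on its right (11481890 to 11482676) was listed at 0 and 0.375 FPKM in Col-0 and at 15.9 and 24.5 in nrpe1-12. In apc8-1 these loci stayed near the Col-0 levels, with 0.0693 ± 0.0122 FPKM for AT5G27845, 0.475 ± 0.192 for AT3G29639 and 0.383 ± 0.183 for XLOC_020069, and none of the 3 was called. SDC was listed at 1.48 and 0 FPKM in Col-0 and at 16.1 and 4.56 in nrpe1-12 (adjusted p = 0.00898), and the call was lost without Col-0 replicate 2 (adjusted p = 0.0525) and without the filter on low values (adjusted p = 0.0512).

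**Figure D1:**
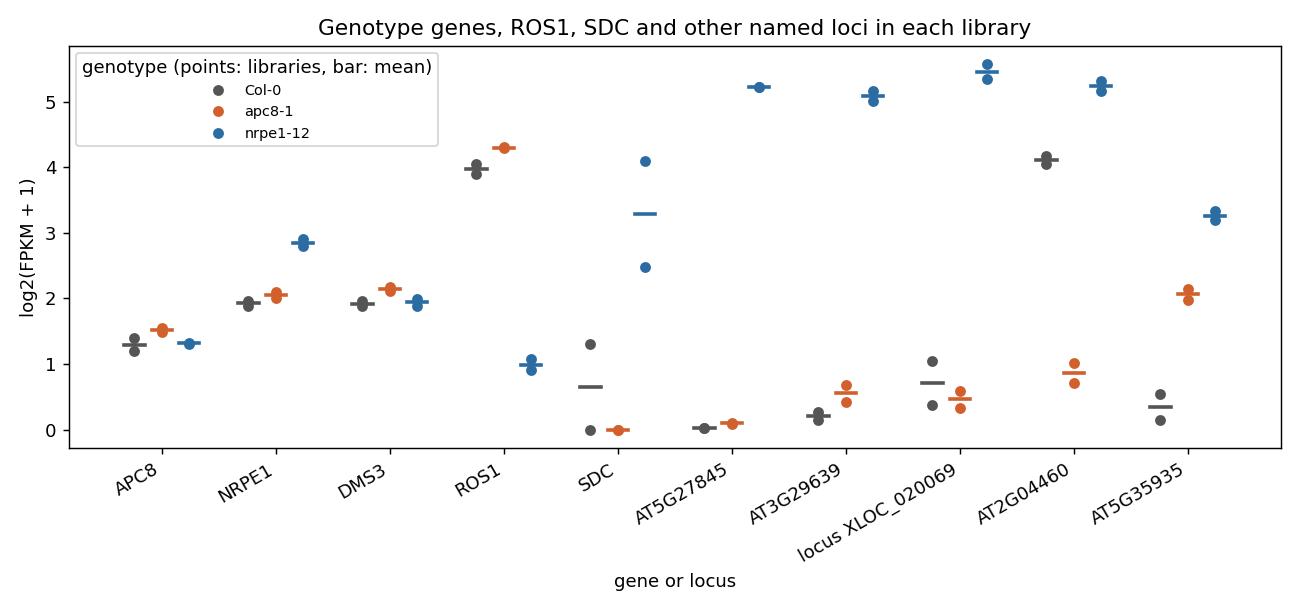
The vertical axis is log2(FPKM + 1) and the horizontal axis lists genes and loci, with 1 point per library and a bar at the mean of the 2 libraries of each genotype. ROS1 lies lowest in nrpe1-12, while AT5G27845, AT3G29639 and XLOC_020069 lie below 2 in Col-0 and apc8-1 and at 5 or above in nrpe1-12.

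In total 2406 loci were called higher and 2273 lower in nrpe1-12, 26.3% of those tested, and 312 and 335 of these changed at least 2-fold. Without Col-0 replicate 1 the number of calls was 2710 in place of 4679, and without Col-0 replicate 2 it was 2787. With organelle and ribosomal RNA genes left out and libraries rescaled to equal summed FPKM of the remaining loci, the median over all loci moved to -0.11. Then 1702 loci were called higher and 3715 lower, so 31.4% of the calls were increases in place of 51.4%. The directions given here are those without that rescaling. Other large increases in nrpe1-12 were TCH4, from 25.0 ± 1.00 to 236 ± 8.49 FPKM (log2 fold change 3.19), BT2, from 4.60 ± 0.555 to 48.4 ± 1.42 FPKM (log2 fold change 3.15), and VSP2, a jasmonate-induced storage protein gene, from 6.30 ± 0.613 to 63.4 ± 0.977 FPKM (log2 fold change 3.14). The unannotated intergenic locus XLOC_016076 (chromosome 3, 18843645 to 18844448) was listed at 0 in the Col-0 and apc8-1 libraries and at 11.5 and 7.76 FPKM in nrpe1-12. Among the decreases, SAG12 was listed at 75.3 and 75.6 FPKM in Col-0 and at 0.638 and 0.838 in nrpe1-12. BGLU21 fell from 16.1 ± 0.703 to 0.715 ± 0.273 FPKM (log2 fold change -3.33) and AT1G62770 from 61.7 ± 5.49 to 7.72 ± 1.27 FPKM (log2 fold change -2.85).

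Of 17 tested jasmonate response genes 11 rose in nrpe1-12 and none fell, also when adjusted over the list alone (median log2 fold change 0.56, camera adjusted p = 1.47e-05, adjusted p = 0.213 with an estimated correlation). Besides VSP2 these included PDF1.2, a defensin gene with near-identical relatives (log2 fold change 2.21), JAZ7 (log2 fold change 1.82) and JAZ9 (log2 fold change 1.76). Of 7 heat shock genes 6 rose and none fell, also when adjusted over the list alone (median log2 fold change 1.43, camera adjusted p = 3.08e-05, adjusted p = 0.213 with an estimated correlation). HSP17.6A rose from 2.14 ± 0.0799 to 14.3 ± 1.94 FPKM and HSP101 from 2.72 ± 0.00163 to 9.28 ± 0.0176 FPKM. Of 14 photosynthesis genes 13 rose and none fell, with all 14 higher when adjusted over the list alone (median log2 fold change 0.53, camera adjusted p = 1.19e-09, adjusted p = 0.301 with an estimated correlation). With quantile normalization the median was 0.14 (camera adjusted p = 0.00629) and 6 of the 14 were called, all higher. The chloroplast share of the FPKM was higher in nrpe1-12 too, while the 6 tested root markers had a median of -0.80, with 1 higher and 3 lower. GAPA, a chloroplast glyceraldehyde-3-phosphate dehydrogenase gene, rose from 313 ± 5.53 to 556 ± 17.7 FPKM. Circadian clock genes moved both ways, 4 higher and 6 lower of 11, with the same counts adjusted over the list alone (camera adjusted p = 0.485). The morning genes CCA1, LHY and RVE8 rose (log2 fold changes 1.47, 1.26 and 1.23), and PRR5, CCR2, LUX, GI and TOC1 fell (log2 fold changes -1.79, -1.68, -0.98, -0.70 and -0.57).

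Of 4 tested flowering genes 2 rose in nrpe1-12, SOC1 and FUL (log2 fold changes 0.89 and 0.91), and none fell, with 3 higher when adjusted over the list alone (camera adjusted p = 0.04997, adjusted p = 0.301 with an estimated correlation). The call of the flowering list was lost without Col-0 replicate 2 (adjusted p = 0.0566), either apc8-1 library (adjusted p = 0.0558 and 0.0562) or either nrpe1-12 library (adjusted p = 0.238 and 0.115), and with pseudocounts of 0.1 and 0.5 (adjusted p = 0.0652 and 0.0551). Of 9 anthocyanin genes 4 rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.0565, 0.301 with an estimated correlation, 0.0397 with quantile normalization and 0.02001 with organelle and ribosomal RNA genes left out). DFR had 10.5 ± 0.524 FPKM in Col-0 and 21.1 ± 0.387 in nrpe1-12. Among 18 salicylic acid defence genes 7 rose and 4 fell, with 8 and 4 adjusted over the list alone and 4 to 7 and 2 to 4 when a library was left out (adjusted p = 0.213), among them WRKY70 (log2 fold change 1.38) and PR1 (log2 fold change 0.82) as increases and PBS3 (log2 fold change -1.09) as a decrease. Among 16 auxin response genes 5 rose and 2 fell, also when adjusted over the list alone, and 3 to 5 and 1 to 2 when a library was left out (adjusted p = 0.211), and IAA14 had a log2 fold change of 1.06. Among 9 cold and abscisic acid genes 1 rose and 4 fell, also when adjusted over the list alone (adjusted p = 0.213), and RD29A had a log2 fold change of -1.11. Of the 6 tested root markers 1 rose and 3 fell, with 1 and 4 adjusted over the list alone and 0 to 1 and 1 to 3 when a library was left out (median -0.80, adjusted p = 0.172), and NRT2.1 had 4.38 ± 1.06 FPKM in nrpe1-12.

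Among 23 tested RdDM genes 3 rose in nrpe1-12 and 1 fell, with 3 and none adjusted over the list alone (camera adjusted p = 0.642), and NRPE1 had the largest change of these. With organelle and ribosomal RNA genes left out 2 rose and 4 fell. The calls of SUVH9 (higher) and CLSY1 (lower) were lost without any 1 of the Col-0 and nrpe1-12 libraries (adjusted p = 0.0864 to 0.179). In the list of DNA methylation maintenance and demethylation 3 genes rose and 1 fell of 15, with the same counts adjusted over the list alone (median 0.06, mean -0.06, adjusted p = 0.412), and the decrease was that of ROS1. The 3 increases, of DML2, SUVH6 and DML3, were lost with organelle and ribosomal RNA genes left out (adjusted p = 0.0590, 0.121 and 0.0640) and without any 1 of the Col-0 and nrpe1-12 libraries. Of the 2 tested genes listed as silenced by DNA methylation SDC was called, also when adjusted over the list alone (adjusted p = 0.655). None of the 17 APC/C genes was called by limma (median -0.07, adjusted p = 0.655), nor any of 8 DNA damage genes (median 0.03, adjusted p = 0.794), adjusting over each list alone called none either, and 1 and 0 of them had an unadjusted p under 0.05. In the G2/M list 2 of 23 genes fell, with 1 adjusted over the list alone (adjusted p = 0.211), and in the S phase list 4 of 20 fell, with 3 adjusted over the list alone (adjusted p = 0.473). When a library was left out these counts were 0 to 2 and 2 to 4. Both G2/M calls were lost without Col-0 replicate 2 (PLEIADE, adjusted p = 0.0556, and KNOLLE, 0.123). The S phase calls of PCNA1 and H3.1e were lost without any 1 of the Col-0 and nrpe1-12 libraries. The histone gene H3.1b, which has near-identical copies, fell by 0.50 on the log2 scale.

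**Figure D2:**
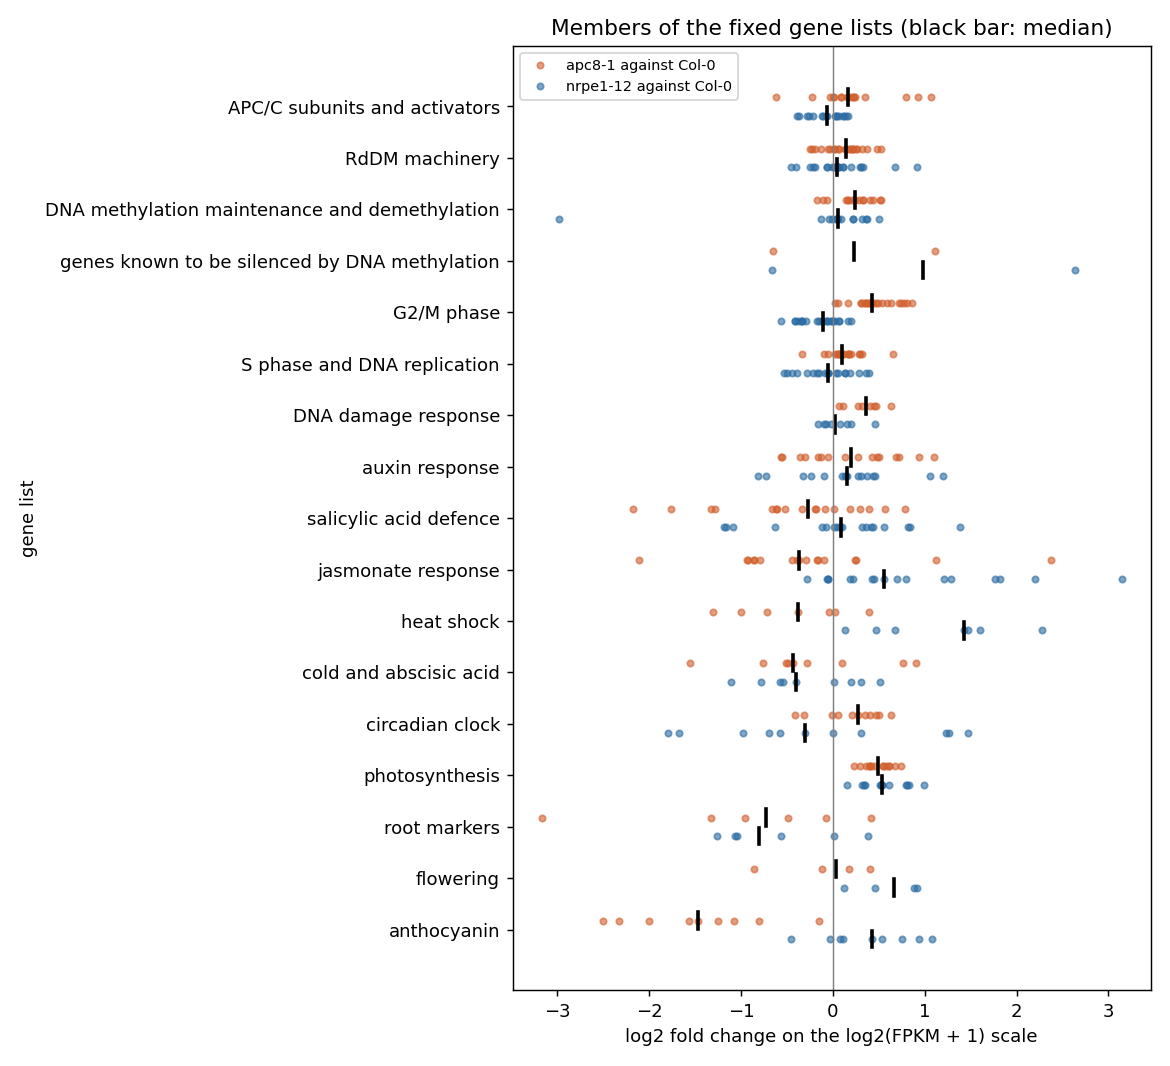
The horizontal axis is the log2 fold change against Col-0 on the log2(FPKM + 1) scale, and each point is a tested member of the gene list named on the vertical axis, with a bar at the list's median for apc8-1 and for nrpe1-12. Anthocyanin genes have a median of -1.46 in apc8-1 and 0.43 in nrpe1-12, and heat shock genes a median of -0.38 and 1.43.

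Pseudogenes and unannotated intergenic loci were called higher in nrpe1-12 more often than other loci. This held for 18 of 70 tested pseudogenes (25.7%, against 13.5% of other loci; Fisher's exact test, adjusted p = 0.0365) and for 24 of 102 intergenic loci (23.5%, against 13.5%; adjusted p = 0.0365). Neighbouring intergenic loci, such as XLOC_013533, XLOC_013534 and XLOC_013535 on chromosome 2 (17485331 to 17488840), count as separate cases in this test. Of the 89 transposable element genes 19 were higher (21.3%, adjusted p = 0.104) and 4 were lower (4.49%, adjusted p = 0.0528), and neither share passed the test. The filter of 1 FPKM in 2 libraries admitted loci that reached it only in nrpe1-12, such as the intergenic locus XLOC_016076. Such loci could be called higher but not lower, so the shares of increases depend on the filter. The pseudogene call was lost without Col-0 replicate 1 (adjusted p = 0.830), Col-0 replicate 2 (0.659), nrpe1-12 library a (0.551) or library b (0.586) and with loci listed at 0 in any library left out (0.0894), and the odds ratio of 2.22 went to 0.661 without the filter on low values. The intergenic call was lost without Col-0 replicate 2 (0.0554), nrpe1-12 library a (0.705) or library b (0.950), when loci listed at 0 in any library were left out (0.531), with a pseudocount of 0.1 (0.0553) and with a filter of 5 FPKM (0.327). Long noncoding RNA genes and antisense loci passed in neither direction (Fisher's exact test, adjusted p = 0.134 to 1). A locus antisense to AT4G08020, for which the strand is uncertain, went from 1.36 ± 0.542 to 38.1 ± 7.20 FPKM (log2 fold change 4.06). AT2G04460, lower in apc8-1, was higher in nrpe1-12 at 36.8 ± 2.55 FPKM (log2 fold change 1.13), and AT5G35935, higher in apc8-1, was higher here too at 8.60 ± 0.599 FPKM (log2 fold change 2.92).

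The direct comparison of both mutants tested whether their effects differ. G2/M phase genes were higher in apc8-1 than in nrpe1-12, while anthocyanin, jasmonate response, heat shock and salicylic acid defence genes were lower. With an estimated correlation the heat shock and salicylic acid defence lists no longer passed camera (adjusted p = 0.0600 and 0.0938). ROS1 was higher in apc8-1 (log2 fold change 3.31, adjusted p = 2.04e-06), and AT5G27845 (log2 fold change -5.13, adjusted p = 1.00e-06), AT2G04460 (log2 fold change -4.38) and VSP2 (log2 fold change -3.53) were lower. NRPE1 was lower in apc8-1 (log2 fold change -0.79, adjusted p = 0.00318), and APC8 and DMS3 were not called (adjusted p = 0.409 and 0.318). In total 1293 loci were called higher in apc8-1 and 2034 lower, 18.7% of those tested, and 100 and 421 differed at least 2-fold. Without nrpe1-12 library a the number of calls was 2042 in place of 3327, and without library b it was 1822. Unannotated intergenic loci were lower in apc8-1 in 29 of 102 cases (28.4%, against 11.3% of other loci; Fisher's exact test, adjusted p = 2.20e-05). That call was lost without nrpe1-12 library a (0.0639) or library b (0.0761), and when loci listed at 0 in any library were left out (0.237). The other classes passed in neither direction (adjusted p = 0.857 to 1). Intergenic loci that passed the filter only through nrpe1-12 could be called lower in apc8-1 but not higher, so their share depends on the filter. Neighbouring intergenic loci count as separate cases here too.

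Of 23 G2/M genes 12 were higher in apc8-1 than in nrpe1-12 and none lower, with 17 adjusted over the list alone and 8 to 12 when a library was left out (median log2 fold change 0.69, camera adjusted p = 6.47e-10, adjusted p = 0.0351 with an estimated correlation). KNOLLE differed by 1.05 on the log2 scale, and CDC20.1, which belongs to the APC/C list and not to this one, by 1.14. All 9 anthocyanin genes were lower in apc8-1, also when adjusted over the list alone (median log2 fold change -2.10, camera adjusted p = 2.54e-10, adjusted p = 0.0351 with an estimated correlation). Of 17 jasmonate response genes 13 were lower and 1 higher, also when adjusted over the list alone (median log2 fold change -0.87, camera adjusted p = 7.74e-10, adjusted p = 0.0351 with an estimated correlation). Of 7 heat shock genes 6 were lower and none higher, also when adjusted over the list alone (median log2 fold change -1.67, camera adjusted p = 8.11e-08, adjusted p = 0.0600 with an estimated correlation). Of 18 salicylic acid defence genes 11 were lower and none higher, with 11 and 1 adjusted over the list alone and 6 to 11 lower when a library was left out (median log2 fold change -0.55, camera adjusted p = 6.65e-06, adjusted p = 0.0938 with an estimated correlation).

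Camera also passed for 4 more lists between the mutants. APC/C genes were higher in apc8-1 in 3 of 17 cases, also when adjusted over the list alone (camera adjusted p = 0.0158, adjusted p = 0.223 with an estimated correlation), S phase genes in 4 of 20, with 5 adjusted over the list alone (adjusted p = 0.0108, and 0.223 with an estimated correlation), and DNA damage genes in 1 of 8, with 3 adjusted over the list alone (adjusted p = 0.0236, and 0.223 with an estimated correlation), and none was lower in these lists. Flowering genes were lower in 3 of 4 cases and higher in none, also when adjusted over the list alone (median -0.74, adjusted p = 0.00859, and 0.162 with an estimated correlation), and 0 to 3 when a library was left out. The APC/C and flowering calls were lost without nrpe1-12 library a (adjusted p = 0.0555 and 0.0587), the DNA damage call without library b (adjusted p = 0.0942), and the APC/C and DNA damage calls with a filter of 5 FPKM (adjusted p = 0.0659 and 0.299). The clock genes were higher in 7 and lower in 4 of 11 cases, also when adjusted over the list alone (adjusted p = 0.0552, and 0.0479 with median-of-ratios scaling), with CCR2 higher in apc8-1 by 2.17 and LHY lower with a log2 fold change of -1.21. Photosynthesis genes were higher in 1 and lower in 3 of 14 cases, with 1 and 4 adjusted over the list alone and 0 to 1 and 0 to 3 when a library was left out (adjusted p = 0.268). The RdDM list had 1 higher and 2 lower of 23 (adjusted p = 0.286), the methylation maintenance list 4 and 1 of 15 (adjusted p = 0.268), and the silenced genes 1 and 1 of 2 (adjusted p = 0.965), each also when adjusted over the list alone. When a library was left out the RdDM counts were 0 to 1 and 1 to 2, with DRM2 lost without nrpe1-12 library a (adjusted p = 0.0548). The methylation maintenance counts were 2 to 3 and 0 to 1, with MET1 and IBM1 lost without either nrpe1-12 library (adjusted p = 0.0727 to 0.0885). The SUVH9 decrease was also lost with quantile normalization (adjusted p = 0.0585), in the fit of 2 genotypes (adjusted p = 0.0645) and without the trend (adjusted p = 0.0645). Auxin genes had 2 higher and 2 lower of 16, with 2 and 4 adjusted over the list alone and 1 to 3 and 0 to 3 when a library was left out (adjusted p = 0.940), cold and abscisic acid genes 2 and 2 of 9, with 4 and 2, and 0 to 1 and 2 (adjusted p = 0.448), and root markers none and 1 of 6, also when adjusted over the list alone (adjusted p = 0.450).

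Loci changed in both mutants mostly moved the same way. BT1, BT2 and TCH4 rose and SAG12 and BGLU21 fell in each, with BT1 at 4.23 ± 0.535 FPKM in Col-0, 39.3 ± 0.702 in apc8-1 and 42.7 ± 1.38 in nrpe1-12. In total 1406 loci were higher in both mutants and 1435 lower in both, against 339 and 367 for independent lists. With organelle and ribosomal RNA genes left out 942 were higher in both and 2219 lower in both, so the even split depends on the scaling. Another 167 loci changed in opposite directions. Across all tested loci, which are not independent, the log2 fold changes correlated at r = 0.63 with a covariance of 0.14, against 0.50 and 0.0106 in simulations where groups without an effect shared the Col-0 libraries. Of the 2841 loci changed in the same direction, 729 also differed between the mutants. Without Col-0 replicate 1 the count of 2841 was 1525, and without Col-0 replicate 2 it was 1599. With a different Col-0 library for each mutant, an alternative added after the results had been seen, it was 1414 or 1442, depending on the assignment (r = 0.517 and 0.521, covariance 0.113 and 0.114).

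**Figure D3:**
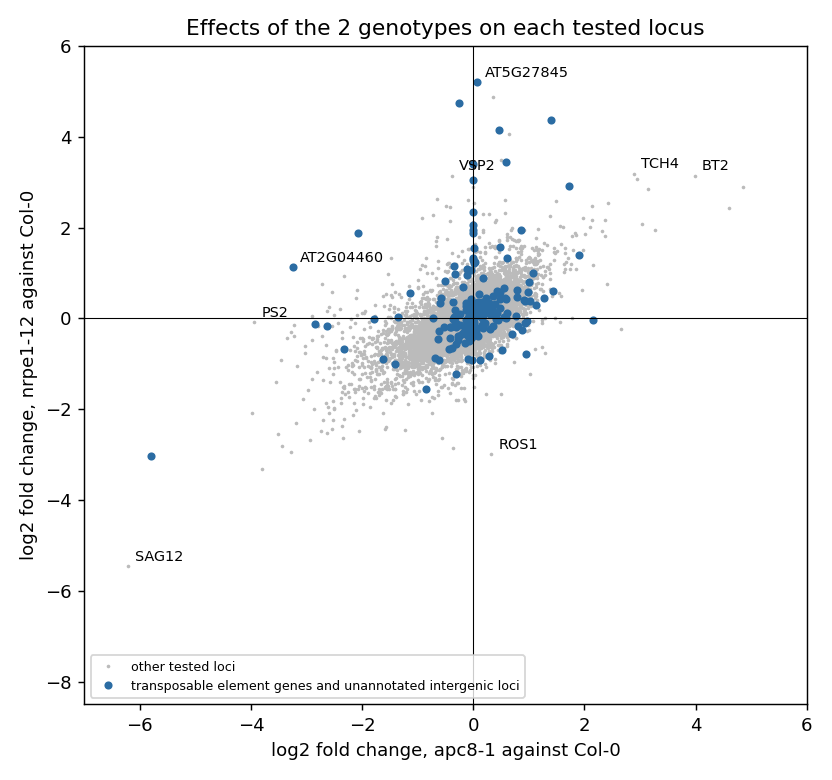
Each point is a tested locus, with the log2 fold change against Col-0 in apc8-1 on the horizontal axis and in nrpe1-12 on the vertical axis, and transposable element genes and unannotated intergenic loci in blue. BT2, TCH4 and SAG12 lie along the diagonal, while AT5G27845, VSP2 and ROS1 lie near the vertical axis and PS2 near the horizontal axis, and loci not reported here are not drawn.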

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

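The alternatives that left out loci listed at 0 or took a different Col-0 library for each mutant were chosen after the results had been seen. Where a library was left out, the lone library of its genotype is assumed to vary like the others. Of 284 named results with a test 247 were called. Of these calls 128 stayed the same under every alternative that tested their locus. Setting aside leave-one-out, the replicate block, the fits of 2 genotypes and the 2-fold minimum, 210 did. Alternatives in which a locus was not tested were skipped, so these counts include calls that some alternatives could not check. With at least 5 FPKM, 206 of the 247 were tested and stayed called, and with loci listed at 0 left out, 219. None of the called named genes reversed, while 16 calls in apc8-1 and 14 in nrpe1-12 had the other sign with quantile normalization. Alternatives based on fragment counts or on the authors' own group comparison were not run, since the table holds FPKM per library. A level of 1 FPKM corresponded to an estimated 13.1 to 17.9 fragments per kilobase, and the effect of depth on the calls was not tested. The replicate block, run on Col-0 and apc8-1, gave 4928 calls, 4685 of them shared.

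With a minimum of 2-fold the calls were 891 in apc8-1, 647 in nrpe1-12 and 521 between the mutants, 310 loci moved the same way in both mutants, and NRPE1 stayed at 0.92 and was no longer past the limit, all by construction of a stricter call. The class results that passed became 4 in nrpe1-12 and 4 between the mutants, for which the cause was not tested. The classes passing Fisher's exact test (1 in apc8-1, 2 in nrpe1-12 and 1 between the mutants) became 1 in nrpe1-12 with a pseudocount of 0.1, and 5, 4 and 3 with no filter on low values. They became 0 in apc8-1 and 1 in nrpe1-12 with at least 5 FPKM, 8 in nrpe1-12 with organelle and ribosomal RNA genes left out, and 0 in nrpe1-12 and 0 between the mutants with loci listed at 0 left out. The last alternative removed intergenic loci that had been called higher in nrpe1-12, such as XLOC_016076 and XLOC_010274. For pseudogenes and the other changes the cause was not tested. The lists passing camera in apc8-1 (3) became 10 with no filter, 6 with at least 5 FPKM, 5 with organelle and ribosomal RNA genes left out, 0 with an estimated correlation and 14 with fry. In nrpe1-12 (4) they became 0 with an estimated correlation and 11 with fry, and between the mutants (9) 3 with an estimated correlation. Fry asks another question, and for the other changes the cause was not tested.

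Leaving out each library in turn gave 3252 to 5168 calls in apc8-1, 2710 to 4857 in nrpe1-12 and 1822 to 2835 between the mutants, and 1525 to 2530 loci that moved the same way in both mutants (r = 0.608 to 0.634). With a different Col-0 library for each mutant the shared count was 1414 and 1442 (r = 0.517 and 0.521), with 1 control sample fewer in each comparison. Among the libraries left out, the lowest counts came from leaving out a Col-0 or nrpe1-12 library, which removes samples. APC8 in apc8-1 ranged from 0.12 to 0.32 and NRPE1 in nrpe1-12 from 0.87 to 0.97. Lists passing ranged from 3 to 7, 3 to 5 and 7 to 10, and classes from 1 to 1, 0 to 2 and 0 to 1, in the same order.

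Among the named results, direction reversed only for values that had not been called and for the odds ratio of pseudogenes in nrpe1-12 (0.661 with no filter). FUL in apc8-1 went to 0.20 with quantile normalization. In nrpe1-12, APC8 went to -0.0504 and DMS3 to -0.0689 with organelle and ribosomal RNA genes left out. With libraries left out in turn, the log2 fold change ranged in apc8-1 from -1.31 to 0 for SDC and from -0.0023 to 0.36 for SEP3, and in nrpe1-12 from -0.0804 to 0.12 for APC8 and from -0.0288 to 0.0689 for DMS3. Between the mutants it ranged from -0.18 to 0.0150 for SHR, from -0.0344 to 0.26 for CASP1 and from -0.0183 to 0.16 for MYB36. The cause was not tested, beyond the removal of a sample.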

Other observations

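The 4 lists described first, and the test of the silenced loci, were chosen after the results had been seen, and NRT2.1 had been seen to be lower before the root marker test was written. The p-values of these 4 lists were adjusted over the 4 alone. That is a milder adjustment than over the 17 fixed lists, so adjusted p-values of the added and fixed lists are not comparable. Phosphate starvation genes were lower in apc8-1. All 12 listed genes other than those in which this was noticed fell, also when adjusted over the list alone, with a median log2 fold change of -1.64 (limma's camera, adjusted p = 3.95e-11, adjusted p = 0.0382 with an estimated correlation). The lipid synthesis gene MGD3 fell from 13.8 ± 1.05 to 1.87 ± 0.157 FPKM (mean ± SD, n = 2), the regulator SPX1 from 66.0 ± 1.59 to 17.2 ± 2.38, and the sulfolipid gene SQD2 from 52.8 ± 0.693 to 23.4 ± 0.852. In nrpe1-12 2 of the 12 rose and 2 fell (adjusted p = 0.262), and all 12 were lower in apc8-1 than in nrpe1-12 (adjusted p = 2.52e-13, adjusted p = 0.0308 with an estimated correlation). The fall in apc8-1 was therefore not limited to the genes in which it was noticed. Root markers had a median of -0.725 in apc8-1, with NRT2.1 and EXPA18 near 0 FPKM, and FIT and FRO2 were called lower, though not without either Col-0 library. The root median was also low in nrpe1-12 (-0.803), where the phosphate list did not pass. Whether phosphate supply or the share of root differed between samples cannot be read from these data.

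Iron deficiency genes other than those first noticed rose in 6 of 9 cases and fell in 2 in apc8-1, with 5 to 6 and 0 to 2 when a library was left out (median 0.56, camera adjusted p = 0.0180, adjusted p = 0.272 with an estimated correlation). OPT3, a shoot iron transporter gene, rose from 12.7 ± 0.598 to 21.6 ± 2.71 FPKM, and FIT, a root regulator of iron uptake, fell from 1.08 ± 0.181 to 0.197 ± 0.187. In nrpe1-12 4 rose and none fell (adjusted p = 0.135). The unadjusted camera p of the iron list in apc8-1 was 0.0135. The methylation maintenance list had 0.0149 there and did not pass when adjusted over the 17 fixed lists (adjusted p = 0.0599). Leaf senescence genes other than SAG12 fell in 9 of 12 cases and rose in 1 in apc8-1 (adjusted p = 2.34e-05, adjusted p = 0.0382 with an estimated correlation), and fell in 7 and rose in 1 in nrpe1-12 (adjusted p = 0.00108, adjusted p = 0.125 with an estimated correlation). NAP, a NAC regulator of senescence, had 194 ± 3.73 FPKM in Col-0, 73.9 ± 1.70 in apc8-1 and 136 ± 7.21 in nrpe1-12. Nitrate induced genes did not pass as a set once the noticed genes were left out, with 4 higher and 2 lower of 10 in apc8-1 (adjusted p = 0.0507, but 0.0379 with organelle and ribosomal RNA genes left out) and 4 higher and 3 lower in nrpe1-12 (adjusted p = 0.262), although LBD37 and LBD38 among the 10 rose in both mutants.

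The 18S ribosomal RNA locus AT3G41768 was given 9827.23 FPKM in apc8-1 replicate 2 and is listed at 0 in the other 5 libraries. The apc8-1 libraries disagree on this locus, so its values of 0 cannot be read as absence of transcript either. Differences between replicates 1 and 2 of Col-0 and of apc8-1 correlated at r = -0.0585 across tested loci, which are not independent. The 43 transposable element and intergenic loci called higher in nrpe1-12 had a median log2 fold change of 1.21 there and 0.07 in apc8-1, where 13 were higher, 2 lower and 28 not called, and 29 were lower in apc8-1 than in nrpe1-12.

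Many loci moved the same way in both mutants. With a different Col-0 library for each mutant the covariance was 0.113 and 0.114 against 0.14, so chance deviations of single Col-0 libraries do not account for the whole of it. The drop was larger than the 7.62% that such deviations gave in simulations. A state common to both Col-0 libraries, such as a shared culture, would survive this split, so it remains open. The prediction written for a shared release of silenced loci was not met. The median change in apc8-1 of the loci called higher in nrpe1-12 was 0.062 of that in nrpe1-12, and ROS1 did not fall in apc8-1. These 43 loci were picked by their rise in nrpe1-12, which favours a small ratio. Some, such as AT2G11240 at 16.2 FPKM, were not silent in Col-0. In apc8-1 13 were higher, 2 lower and 28 not called, so the ratio cannot decide whether a shared release contributed. For comparison, 1406 of all 2406 loci called higher in nrpe1-12 were also higher in apc8-1, counts that depend on the scaling. A lower share of root in both mutants had been given up beforehand if root markers moved both ways, and they did (medians of -0.803 in nrpe1-12 and -0.725 in apc8-1, with SCR higher in both), but that rests on SCR alone, which leaves also express and whose call was lost in apc8-1 without any 1 of the Col-0 and apc8-1 libraries (adjusted p = 0.0583 to 0.0910) and in nrpe1-12 with organelle genes left out (0.28, adjusted p = 0.0768) or any 1 of the Col-0 and nrpe1-12 libraries left out (adjusted p = 0.0511 to 0.138), so a contribution may remain. A different hour of harvest cannot be told apart from the genotypes, because clock genes moved 4.84 times as much as the median locus in nrpe1-12 and 1.60 times in apc8-1 and no harvest time is given, although another hour for Col-0 alone would move them alike in both mutants, and all 11 differed between the mutants, with CCR2 at 0.50 in apc8-1 and -1.68 in nrpe1-12; a common effect of both alleles also remains open, untested.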
